A study of Mus musculus with 2 samples.

How the data were processed

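RNA-seq libraries from mouse megakaryocyte-erythroid progenitors were analysed, 1 group of 2 biological replicates as numbered in the labels. Per the labels the RNA was poly(A) selected and the assembly was mm10, and a text file deposited with each sample names GENCODE M4 as the annotation. The aligner, the quantification program and their versions are not given in the sources used here; the column names are those RSEM writes. Strand handling is likewise not given, so whether reads of overlapping antisense genes were separated is not known.

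Each library has a gene table and a transcript table. Per the file headers, the authors estimated an expected count per gene and transcript, which shares reads that fit several genes among them and need not be whole. The deposited TPM values divide these by effective length and scale each library to a sum of 1000000, and the deposited FPKM values are per kilobase and per 1000000 fragments. The deposited percent columns give each transcript's share of its gene. The authors' TPM intervals cover quantification error within 1 library; their level is not stated in the headers. They belong to the posterior mean, and the TPM itself lay outside its own interval for 341 genes in replicate 1 and 502 in replicate 2 among those at a TPM of 1 or more.

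Of 43346 gene identifiers, 42462 matched GENCODE M21 by identifier without version, which gave symbols, gene types and GRCm38 coordinates; 884 did not match and entered no list. The 97 spike-in rows had 0 counts and the 26248 rows with numeric identifiers 1 count in replicate 1 and 0 in replicate 2; both stayed out of library totals. Spread was estimated with edgeR 4.0.16 (R 4.3.3) on expected counts rounded to whole numbers, with TMM scaling (factors 0.98 and 1.02), filterByExpr and an intercept-only design. This filter needs counts in both libraries, so a gene present in 1 library alone enters no list shift. Log2 CPM used a prior count of 2. DESeq2 1.42.0 gave alternative size factors and dispersions. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

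There were 23 gene lists, 20 by symbol and 3 by name pattern, fixed before the data were examined, as were the 22 pairs, the 24 transcript genes, the tests and the alternatives. One list member had no matched symbol and entered no list. Values of some named members are not reported here. The rule for genes the text may name took, of each list, the 4 highest and 2 lowest members by mean TPM (ties at 0 included) and the 2 with the largest difference between libraries at a mean TPM of 5 or more, the 15 most abundant genes, the 10 genes farthest apart in each direction, and all members of the pairs, gate antigens, sex label, transcription factors and transcript genes. List levels were compared as medians of log2(mean TPM + 1) with 100000 permutations of membership, two-sided, Benjamini-Hochberg adjusted over 7 pairs with a threshold of 0.05. List levels were also ranked among 10000 random lists of protein-coding genes, and shifts between replicates among 10000 random lists matched in 20 expression bins. A list stood apart outside the central 95% of random lists, and this was asked of 22 lists with no adjustment. Ratios of gene pairs used a pseudocount of 0.01 TPM. A pair was called when the ratio had the same sign in both libraries, its mean log2 exceeded 1 in size and the TPM intervals were separate in each library.

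The steps were tested on simulated data. For the comparison of replicates, with 13546 genes and 200 changed, true coefficients of variation of 0.1 and 0.2 were estimated at 0.14 and 0.219, above the values planted. The 2-fold rule without its interval condition found 54% and 49% of genes changed 2-fold and 100% and 99% of those changed 4-fold, and called 0% and 1.62% of unchanged genes with 100 counts or more. For list shifts over 12402 genes, a planted log2 change of 0.3 in 20 members was found in 82.5% of 200 simulations, and unchanged lists were called higher in 3.5% and lower in 2%. For list levels over 21474 genes, a planted log2 difference of 2 was found in 68% of simulations and one of 4 in 99.5%. Lists without a planted difference were called higher in 3.5% and lower in 3.5%. The simulated lists were random genes, unlike marker genes that vary together.

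The p-values across genes describe these libraries. Counting floors cover counting error only, and the TPM intervals cover quantification error within 1 library. No molecular identifiers are mentioned in the labels. Alternatives changed the detection threshold, unit, pseudocount, filter, scaling, statistic and background, or left out 1 library. Corrections for GC content and length, and a granulocyte and monocyte list without 5 late granule genes, were added after seeing the data.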

Results

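Poly(A)-selected RNA was sequenced as paired ends from primary mouse megakaryocyte-erythroid progenitors (MEP), cells that give rise to red cells and to the megakaryocytes that shed platelets. They are labelled adult female C57BL/6J, 5 weeks old, and a label describes them as negative for CD34, naming lineage markers and CD16/32 in the same phrase. There was 1 group with 2 biological replicates, listed as separate biosamples under the same donor identifier, so no comparison between conditions exists. Estimated counts on annotated genes summed to 79539457 in replicate 1 and 65305321 in replicate 2. A count of 0 therefore allowed up to 0.0377 and 0.0459 CPM (counts scaled to a library of 1000000), counting error only. Values below are TPM (transcript abundance scaled for length and library) with the SD between the 2 libraries, and coordinates are on GRCm38.

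The libraries shared most of their expressed genes. A TPM of 1 or more in both was found for 10698 of 43346 annotated genes, of which 10061 were protein-coding (46.9% of 21474). A further 213 protein-coding genes reached that level in replicate 1 alone and 323 in replicate 2 alone. Ribosomal protein genes held 21.8% and 21.4% of all TPM, and Rplp1 was the most abundant gene at 29271 ± 4107 (SD, n = 2). Besides Rplp1, the 15 most abundant genes included Ptma at 11926 ± 899, the glycolytic enzyme gene Gapdh at 9818 ± 930 and the histone gene Hist1h2ao at 10700 ± 2747, which shares reads with near-identical copies and is uncertain. Across protein-coding genes, log2(TPM + 1) correlated between libraries with Pearson r = 0.994 and Spearman rho = 0.975; genes are not independent replicates.

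The question the label poses is how the genes of the erythroid and megakaryocytic lineages stood in these cells, and beside them those of other blood lineages. Transcription factors of the fixed erythro-megakaryocytic list were abundant as a group. How specific each is to these lineages was not tested, so their level does not by itself identify the cells. Of 22 fixed factors, 21 were detected in both libraries, and their median TPM was 108 ± 5.47 (SD, n = 2). Ldb1, a scaffold of the Gata1 and Tal1 complex, was at 667 ± 104, and Zfpm1, the Gata1 cofactor also known as Fog1, at 549 ± 187. Lmo2 was at 452 ± 51.0, Runx1 at 321 ± 31.1, Klf1 at 123 ± 0.389, Gfi1b at 89.1 ± 16.2, Tal1 at 63.1 ± 14.1 and Nfe2 at 88.6 ± 4.30. Sox6 was lowest, at 0.855 ± 0.417.

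Gata2 exceeded Gata1 in both libraries. Gata2 (ENSMUSG00000015053.10, chromosome 6, 88193891 to 88207032) was at 306 ± 104 and Gata1 (ENSMUSG00000031162.10, chromosome X, 7959260 to 7978071), the factor that replaces Gata2 on chromatin as erythroid cells mature, at 37.1 ± 12.2, a difference of 8.23-fold. The log2 ratio of Gata1 to Gata2 was -3.04 ± 0.01 (SD, n = 2), and -3.84 in counts not corrected for length. Gata1 was also below Spi1, the myeloid factor PU.1, with a log2 ratio of -3.32 ± 0.77, while Klf1 exceeded Fli1 with a log2 ratio of 1.74 ± 0.26, which was 0.55 in counts not corrected for length. Fli1 and Erg (-0.17 ± 0.01), Runx1 and Runx3 (-0.22 ± 0.01), and Stat5a and Stat5b (-0.03 ± 0.01) lay close together in TPM; in counts not corrected for length the first of these was 0.78 and the last -0.63. Gfi1b and Gfi1 had no common order, since Gfi1 was higher in replicate 1 and Gfi1b in replicate 2.

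**Figure D1:**
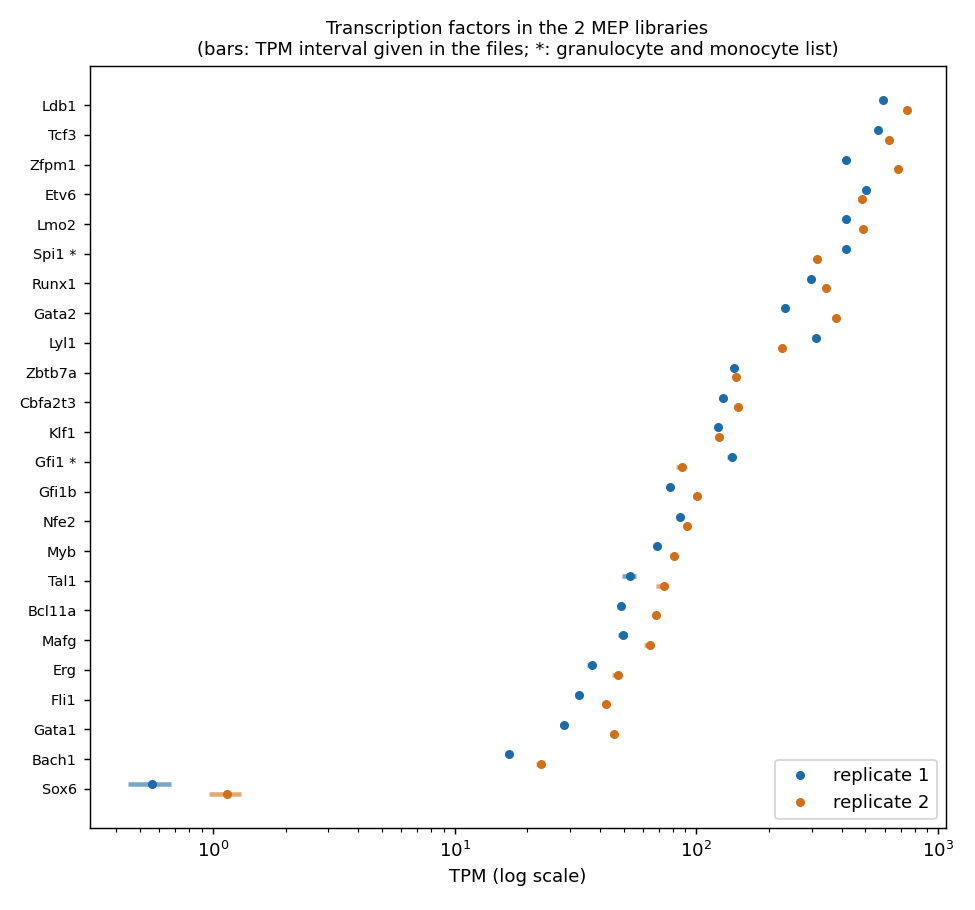
TPM on a log axis of the 22 erythro-megakaryocytic transcription factors and of Spi1 and Gfi1 in each library; points are the library values and bars the TPM intervals given in the files. Gata2 (233 and 379) lies above Gata1 (28.5 and 45.8) in both libraries.

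Genes of the erythroid list spanned a wide range. The 24 genes had a median TPM of 15.5 ± 2.67 (SD, n = 2), and 21 were detected in both libraries. The list median lay at percentile 99.7 of random lists of protein-coding genes, and at percentile 41.8 against genes detected in both libraries alone. In this last comparison, here and below, undetected members stayed in the list, so it places lists with undetected members lower. The highest erythroid members were Blvrb (biliverdin reductase B) at 227 ± 31.6 and the carbonic anhydrases Car2 at 176 ± 27.3 and Car1 at 97.1 ± 15.2. The water channel gene Aqp1 was at 59.8 ± 14.5. The erythropoietin receptor gene Epor was at 46.9 ± 7.54. The membrane skeleton gene Epb42 was among the lowest members, at 0.98 ± 0.198. Alas2, the erythroid first enzyme of heme synthesis, was at 0.385 ± 0.0495 against 121 ± 56.8 for its housekeeping counterpart Alas1, although 12 of 13 heme synthesis genes were detected and their median was 41.3 ± 2.18. Adult globin mRNA was present, with Hba-a1 at 688 ± 269 and Hbb-bs at 497 ± 306, whereas the embryonic genes Hba-x, Hbb-bh1 and Hbb-y had no counts. Globin genes are near-identical copies, so their split is uncertain.

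Megakaryocyte and platelet genes spanned a wide range. The list median was 6.97 ± 1.60 (SD, n = 2) and 18 of 24 members were detected. It lay at percentile 97.0 of random lists of protein-coding genes, inside the central 95%, with 97.6 and outside it in replicate 2 alone. Against genes detected in both libraries it lay at 2.27, below the central 95%, with undetected members kept in the list. That unlike comparison does not show that the detected members were low among detected genes. Fermt3 (kindlin-3) was at 648 ± 9.48, the integrin gene Itga2b (CD41) at 163 ± 68.5, Nbeal2 at 74.2 ± 0.396 and Pear1 at 63.1 ± 19.0. How specific each of these genes is to megakaryocytes was not tested. Mpig6b was at 0.03 in each library and Gp6, the platelet collagen receptor gene, had no counts. Stem and multipotent progenitor genes had a median of 9.02 ± 1.39, led by Hoxa9 at 79.7 ± 15.5, Meis1 at 63.6 ± 26.2, Cd27 at 49.5 ± 10.7 and Hlf at 48.1 ± 20.1, with Slamf1 at 0.475 ± 0.276.

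Genes of granulocytes and monocytes were the most abundant lineage list in the libraries labelled MEP. The median of its 22 members was 182 ± 69.6 (SD, n = 2) and 21 were detected. Mpo (myeloperoxidase, chromosome 11, 87793581 to 87804413) was at 8329 ± 2555, and the neutrophil serine protease genes Prtn3, Elane and Ctsg were at 7893 ± 3829, 6481 ± 3032 and 1052 ± 352. Mpo and Prtn3 were among the 15 most abundant genes of all. The lowest members were Cd14 at 5.17 ± 3.02 and Fcgr1 at 0.085 ± 0.0778. Together the list took 3.44% of TPM in replicate 1 and 2.01% in replicate 2, against 0.0746% and 0.0943% for the erythroid list. The erythroid list holds no globin genes. The separate list of globins and their chaperone took 0.114% and 0.248%.

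The erythroid list lay below the granulocyte and monocyte list by -3.54 in median log2(mean TPM + 1), with -3.93 in replicate 1 and -2.91 in replicate 2 (permutation of list membership, two-sided, p = 0.00044, adjusted p = 0.00154 over 7 pairs of lists). The megakaryocyte and platelet list lay below the granulocyte and monocyte list by -4.52 (permutation p = 5e-05, adjusted p = 0.00035), with -5.01 in replicate 1 and -3.88 in replicate 2. The erythroid list exceeded the T and NK cell list by 3.34 (permutation p = 0.00257, adjusted p = 0.006); with members detected in both libraries alone, 3 of them in the T and NK cell list, the difference was 0.45 with adjusted p = 0.791. The other 4 pairs did not pass: erythroid minus megakaryocyte and platelet was 0.98 (adjusted p = 0.578), erythroid minus stem and multipotent progenitor 0.79 (adjusted p = 0.785), megakaryocyte and platelet minus stem and multipotent progenitor -0.19 (adjusted p = 0.862), and erythroid minus B cell 1.32 (adjusted p = 0.399), all by the permutation test. These tests run across genes, which are not independent replicates; an exact two-sided sign test over 2 libraries cannot go below p = 0.5.

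**Figure D2:**
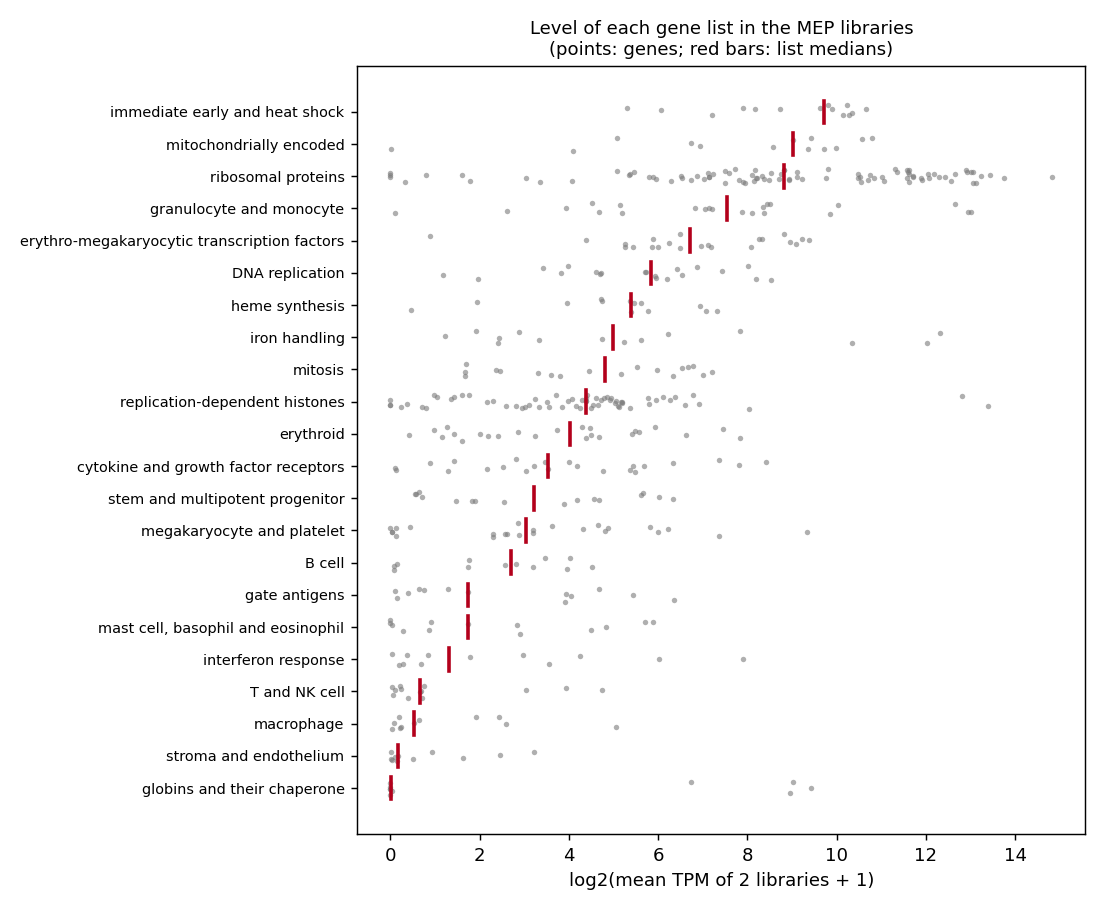
Level of each fixed gene list as log2(mean TPM of the 2 libraries + 1); points are genes and red bars list medians. The granulocyte and monocyte median (7.55) lies above those of the erythroid (4.02), stem and multipotent progenitor (3.22) and megakaryocyte and platelet (3.03) lists.

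Antigens used to gate such cells were read at the mRNA level. Cd34 (chromosome 1, 194938819 to 194961279) was at 80.5 ± 16.1 (SD, n = 2) and Kit, the stem cell factor receptor gene, at 42.1 ± 4.67. The genes of CD16/32, Fcgr3 and Fcgr2b, were at 15.6 ± 9.42 and 14.0 ± 3.84, and Itgam (CD11b) at 14.3 ± 4.53. Ptprc (CD45) was at 24.5 ± 2.62. Cd3e, Cd4, Cd8a, Il7r and Ly6a had means below 1, and Ly6g was at 1.47 ± 1.90. The mRNA level does not give the surface protein on which a gate acts. For the sex label, Xist was at 19.4 ± 6.13, Uty at 0.045 ± 0.0212, and Ddx3y, Eif2s3y and Kdm5d had no counts.

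Genes of DNA replication, mitosis, iron handling and cytokine receptors were mostly detected. All 20 DNA replication genes and all 18 mitosis genes were detected in both libraries, with median TPM of 55.3 ± 0.00354 and 27.8 ± 5.49 (SD, n = 2). Each SD is between the list medians of the 2 libraries and does not measure how single genes vary. Of the DNA replication genes, 15 were higher in replicate 1 and 5 in replicate 2. The replication licensing gene Cdt1 was at 368 ± 16.5 and the helicase genes Mcm2 and Mcm3 at 294 ± 15.5 and 260 ± 48.8. Cenpa was at 148 ± 10.8 and Aurkb at 128 ± 50.1, with Ccnb1 and Cenpe at 2.21 ± 0.742 and 2.21 ± 0.332. Of 14 iron handling genes, all were detected, led by the ferritin genes Fth1 at 5101 ± 303 and Ftl1 at 4187 ± 888. Among cytokine and growth factor receptors, Tnfrsf1a was at 340 ± 125, Csf2ra at 225 ± 62.9 and Il3ra at 165 ± 32.5, and 20 of 23 were detected. All 4 lists lay above the central 95% of random lists of protein-coding genes in level; against genes detected in both libraries alone, DNA replication was at percentile 99.7, iron handling at 88.0, mitosis at 84.3 and receptors at 14.3.

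Of the 22 fixed gene pairs, 16 differed by more than 2-fold in the same direction in both libraries with separate TPM intervals. Jak1 exceeded Jak2, the kinase of the erythropoietin receptor, by 45.3-fold, and the methylcytosine dioxygenase gene Tet3 exceeded Tet2 by 17.3-fold. Mcl1 exceeded Bcl2l1 by 16.3-fold, Ccnd3 exceeded Ccnd2 by 11.4-fold, and Ezh2 exceeded Ezh1 by 6.37-fold. Lmo2 exceeded Lmo4 by 5.34-fold, Lyl1 exceeded Tal1 by 4.27-fold and Nfe2 exceeded Nfe2l2 by 3.56-fold. Bcl2l1 exceeded Bcl2 by 3.06-fold in TPM; in counts not corrected for length the mean log2 ratio was -0.061. Several of these ratios also moved by more than 1.5 times in counts not corrected for length: the mean log2 ratio of Jak2 to Jak1 went from -5.50 to -2.18, of Ccnd3 to Ccnd2 from 3.52 to 1.58, of Mcl1 to Bcl2l1 from 4.03 to 2.92 and of Lmo2 to Lmo4 from 2.42 to 1.47.

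Among 24 genes examined by transcript, 22 had the same most abundant transcript in both libraries. Runx1-203 held 94.5% ± 0.505 (SD, n = 2) of Runx1 TPM, Zfpm1-201 98.8% ± 0.0554, Myb-203 89.8% ± 0.01 and Gfi1b-204 93.0% ± 2.43. The exceptions were Gata2, where Gata2-201 held 48.4% in replicate 1 and 63.2% in replicate 2, and the transferrin receptor gene Tfrc, where Tfrc-201 held 79.5% and 20.7%. For Etv6 and Epb41 the most abundant transcript was annotated as a processed transcript, Etv6-203 with 64.5% ± 8.22 and Epb41-215 with 84.4% ± 0.368.

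The biological coefficient of variation, as edgeR names it, was 21.8% between the replicates over 13546 genes. Whether they came from separate animals or pools is not given in the sources used here, so this spread may be partly technical. Their counts differed with a chi-square of 206 per degree of freedom, computed to ask whether the libraries differ by more than sampling noise. At this depth separate samples exceed such noise in any case, so no conclusion is drawn from it. Of 7653 protein-coding genes with a mean TPM of 5 or more, 105 (1.37%) were more than 2-fold apart with separate TPM intervals, 79 higher in replicate 1 and 26 in replicate 2. Simulated libraries with a coefficient of variation of 0.2 had 1.62% of unchanged genes with 100 counts or more apart without the interval condition. The number apart therefore does not by itself show changed genes. The simulated value lies near the estimate from these same 2 libraries, changed genes included. The simulation thus cannot decide whether the number apart exceeds replicate spread. On log2 TPM in place of TMM-scaled CPM the split was 54 and 41, with 75 genes in common. One library stands against 1, so these differences have no replicate check.

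Replicate 1 was higher in the immediate early and heat shock, granulocyte and monocyte, B cell and mitosis lists. The heat shock genes Hspa1a and Hspa1b were 5.88-fold and 5.01-fold higher there, although they are near-identical copies and their split is uncertain, and Fos was at 1741 against 733. Retnlg (6.15-fold), Ly6d (4.95-fold), Mmp9 (4.74-fold) and the B cell factor gene Pax5 (3.70-fold) were among the 10 largest. The median log2 shift of the immediate early and heat shock list was 0.75, with 11 of 14 members higher in replicate 1, and that of the granulocyte and monocyte list 0.68, with 20 of 21 higher. The B cell list shifted by 0.88 (9 of 11 higher) and the mitosis list by 0.37 (16 of 18 higher). Each of these 4 lists lay above the central 95% of 10000 random lists matched on expression. Interferon response (0.42), iron handling (0.24) and receptor genes (0.17) did so too, and lost that place when the mean replaced the median. Interferon response (percentile 95.6) and iron handling (96.1) also lost it among members at a TPM of 5 or more, and iron handling (94.5) and receptors (97.4) with GC content and length corrected, a correction added after seeing the data. Receptors lost it on log2(TPM + 1) as well (90.7) and against random lists not matched on expression (95.8).

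Replicate 2 was higher in globin, megakaryocyte, stem cell and erythroid genes. Hbb-bs and Hba-a2 were 2.36-fold and 2.34-fold higher there, and Thbs1, which encodes the platelet granule protein thrombospondin 1, 2.66-fold. The globin list shifted by -1.03, with all 4 members that passed the count filter, of 10 measured, higher in replicate 2; these are near-identical copies that share reads. Among the others, the megakaryocyte and platelet list shifted by -0.62 (17 of 19 higher in replicate 2) and the stem and multipotent progenitor list by -0.58 (14 of 15). In these lists, Flt3 was at 15.4 in replicate 1 and 33.4 in replicate 2, and Itga2b at 115 and 211. Replication-dependent histones, whose mRNAs mostly end without a poly(A) tail, shifted by -0.27, with 46 of 59 members higher in replicate 2. Their share of TPM was 2.20% in replicate 1 and 1.74% in replicate 2, led by the near-identical Hist1h2ao (12643 and 8757) and Hist1h2ap (7707 and 6660). The median log2 difference of 5 non-coding RNAs without a long tail, chosen after seeing the data, was -0.99. Erythro-megakaryocytic transcription factors shifted by -0.19 and the erythroid list by -0.22; these 6 lists lay below the central 95% of random lists. Mitochondrially encoded genes shifted by -0.17, at percentile 2.28. Members that share reads with nuclear copies make this shift uncertain. The TPM of mt-Atp6, which entered it, was 137 and 73.8 in replicates 1 and 2, below its own interval in each library. With the mean in place of the median, the erythroid list (percentile 8.63) and the mitochondrial list (percentile 3.53) no longer stood apart, nor did the mitochondrial list against random lists not matched on expression (percentile 8.80).

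**Figure D3:**
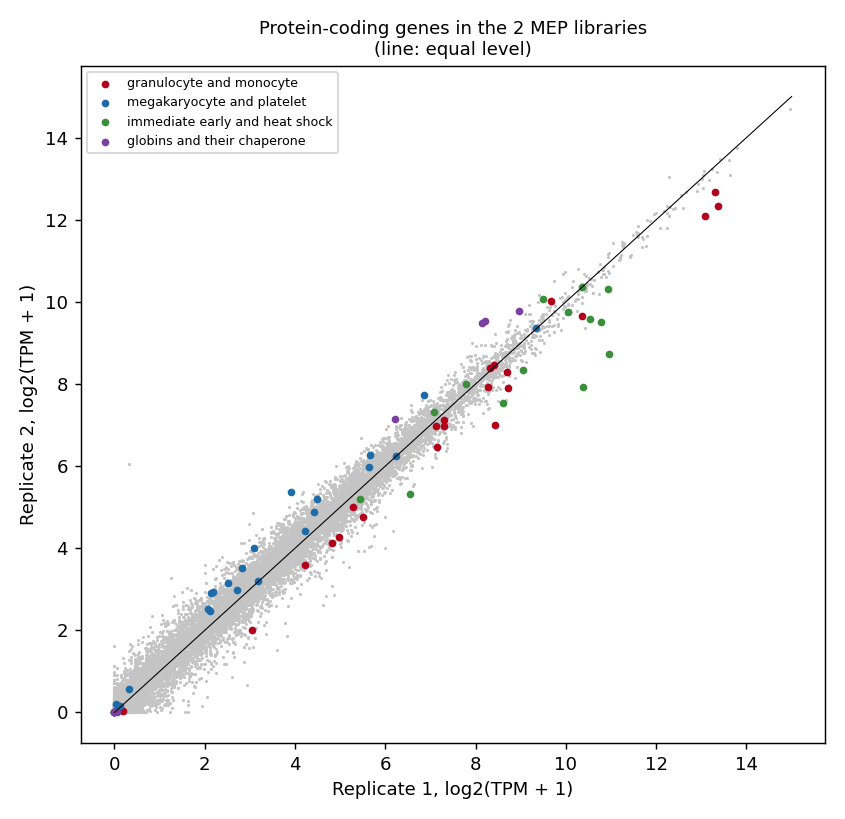
Each point is a protein-coding gene, with log2(TPM + 1) in replicate 1 on the x axis and replicate 2 on the y axis; 4 fixed lists are coloured and the line marks equal level. Genes of the immediate early and heat shock list and of the granulocyte and monocyte list lie mostly below the line, adult globin and megakaryocyte genes mostly above it.

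**Figure D4:**
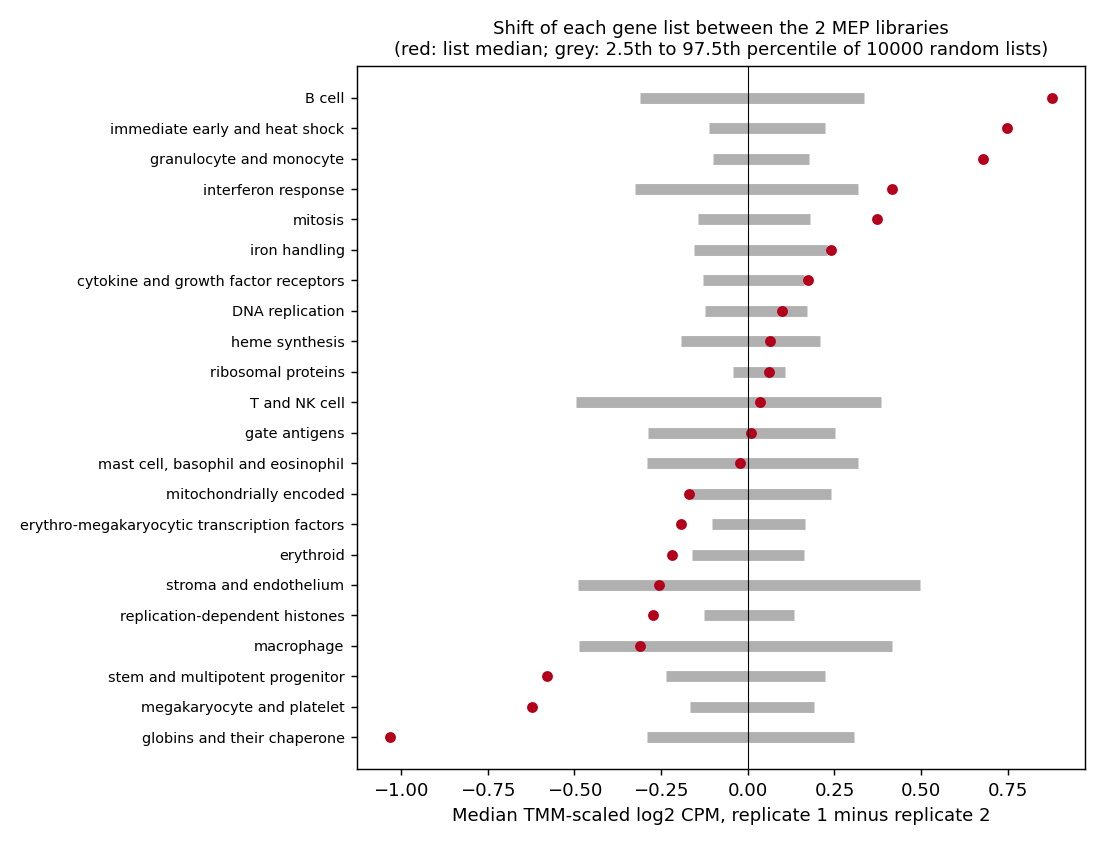
Median difference in TMM-scaled log2 CPM, replicate 1 minus replicate 2, of each fixed list (red), with the central 95% of 10000 random lists (grey). The B cell list (0.88) is the highest and the globin list (-1.03) the lowest.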

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

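Of the tests in this part, the correction of the list difference for GC content was set before its result was seen; the other tests were chosen only after the results were seen. The design holds 1 group, so no explanation by condition was tested. Explanations by cell composition were set only against marker genes within these 2 libraries.

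Signal was also found in RNAs outside the protein-coding comparisons. With no control samples it was set only against the limit that a count of 0 allows, in CPM, which any RNA with more than a few counts exceeds. The non-coding gene Gm42418 (chromosome 17, 39846958 to 39848788) was at a TPM of 2332 in replicate 1 and 11381 in replicate 2. The mitochondrial ribosomal RNA genes summed to 155 and 331, and the immunoglobulin constant genes to 146 and 113.

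Gm42418 was 4.55-fold higher in replicate 2. A weaker selection of polyadenylated RNA in that library may account for it: the median log2 difference of mt-Rnr1, mt-Rnr2, Rn7sk, Rmrp and Rpph1, RNAs without a long poly(A) tail, was -0.99, replicate 1 minus replicate 2. All 5 were higher in replicate 2, from -1.98 for Rmrp to -0.19 for Rn7sk. Some of these RNAs had been looked at before the test was set. Other annotated classes of small RNA, all with low counts, had no common direction. Summed TPM in replicates 1 and 2 was 150 and 82.8 for snoRNA and 88.6 and 22.4 for miRNA. It was 108 and 183 for scaRNA and 5.7 and 10.9 for snRNA. The snRNA sums rest on 13 and 9 counts, so they give no direction. Replication-dependent histones, also mostly without a tail, had a median shift of -0.27 with 46 of 59 members higher in replicate 2, while the near-identical Hist1h2ao and Hist1h2ap, which hold most of the list's TPM, were higher in replicate 1.

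The granulocyte and monocyte list lay above the erythroid list in libraries labelled MEP. The difference, erythroid minus granulocyte and monocyte, was -3.54 before correction for GC content, with -3.93 in replicate 1 and -2.91 in replicate 2. After correction it was -3.93 (permutation p = 3e-05), with -4.45 in replicate 1 and -3.38 in replicate 2. It was no smaller in size after the correction, which argues against the GC content of the genes as its cause. Mature neutrophils carried over would bring late granule transcripts, but Mpo, Elane, Prtn3 and Ctsg summed to at least 8.90 times the TPM of Ltf, Camp, Ngp, S100a8 and S100a9 (1666 and 1894 in replicates 1 and 2), genes picked after their values were seen, and without those late genes the difference was -3.13 (permutation p = 0.00292), which argues against such cells as the whole cause and leaves a part open. Cells outside the stated gate, in a mixed or mislabelled sample, remain a candidate explanation: Cd34 mRNA was at 69.1 or more in both libraries and above Gata1 in each. Cd34 mRNA in cells without the surface protein would give the same reading, so this stays a hypothesis.

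The granulocyte and monocyte list was higher in replicate 1 and the megakaryocyte and platelet list in replicate 2, a gap of 1.30 in median log2 shift. The gap was 1.17 after correction for GC content and length, which argues against those trends as the whole cause. A larger share of granulocytic cells of every stage in replicate 1 would move early and late granule genes alike, yet the median shifts of 4 early and 5 late genes were 0.91 apart (early 0.95, late 0.04) with ranges that did not overlap, while Retnlg, Mmp9 and Cyp4f18, also genes of late neutrophils, were 6.15-fold, 4.74-fold and 4.23-fold higher in replicate 1, so late genes did not move as one. A lower granulocytic share in replicate 2 that raised all other cell types alike was also set against the data, and the B cell and megakaryocyte lists were 1.5 apart (permutation p = 0.00016). A different mix of progenitor stages or of mature neutrophils in the 2 sorts, or different handling given the heat shock genes, was not tested.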

How the results depend on the processing

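The alternatives below were planned except the corrections for GC content and length and the list without 5 late granule genes, which were chosen after seeing the data. Counts of detected genes stayed within 1.5 times of 10698 and 10061 under all alternatives run. The difference between the erythroid and the granulocyte and monocyte lists kept its sign and its side of the threshold under all 9 alternatives, from -2.91 without replicate 1 to -3.93 without replicate 2 and with GC content corrected. The correlation was 0.992 and 0.984 with pseudocounts of 0.1 and 0.01, 0.986 among genes at a TPM of 1 or more and 0.989 on scaled counts. The coefficient of variation was 21.9% by library size alone, 28.7% without a filter, 18.2% at 100 counts or more and 19.0% with DESeq2. Genes more than 2-fold apart numbered 270 (172 and 98 higher in replicates 1 and 2) at a mean TPM of 1 or more, 45 (38 and 7) at 20 or more, fewer or more genes being tested, and 41 higher in replicate 2 on log2 TPM. Lists above the central 95% of random lists in level fell from 12 to 6 against detected genes alone, a higher background, with undetected members kept in the lists. Lists higher in replicate 1 fell from 7 to 4 with means. With detected members alone, erythroid minus T and NK cell was 0.45 and erythroid minus stem -0.18; megakaryocyte minus stem was 0.12 with means and 0.075 with GC content corrected, none of these near the threshold. Erythroid minus megakaryocyte and platelet was 0.41 with detected members alone, 0.43 with means and 0.25 with GC content corrected. With GC content corrected, erythroid minus B cell was 0.60 and erythroid minus stem 0.32. These differences did not pass the threshold either. In counts not corrected for length Bcl2l1 over Bcl2 was -0.061. Where no construction is named, the cause was not tested. No paired analysis was possible because there is 1 group.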

Other observations

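Some genes of mast cells, basophils and eosinophils were detected. Of 13 fixed genes, 7 were detected in both libraries, with a list median TPM of 2.32 ± 0.24 (SD, n = 2). The median was at percentile 72.1 of random lists of protein-coding genes. It was at 0.01 against genes detected in both libraries alone, a comparison lowered by the undetected members kept in the list. The basophil protease gene Prss34 was at 58.6 ± 2.43, the histamine-forming enzyme gene Hdc at 50.9 ± 4.08, and the eosinophil granule genes Epx and Prg2 at 27.6 ± 1.67 and 21.5 ± 6.09. Il5ra and Tpsb2 had no counts. The list did not stand apart between the replicates, with a median shift of -0.02 at percentile 40.5.

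Lists of other cell types and of the interferon response lay within the central 95% of random lists of protein-coding genes in level. Against genes detected in both libraries alone, the B cell list was at percentile 2.55 and the interferon response list at 0. Undetected members stayed in the lists, which lowers these percentiles. The T and NK cell, macrophage, and stroma and endothelium lists had medians below a TPM of 1. Their percentile of 0 was thus fixed in advance, and no conclusion is drawn from it. Of 12 B cell genes 9 were detected, led by Cd79a at 22 ± 14.6 (SD, n = 2), with the surrogate light chain genes Igll1 and Vpreb1 at 14.6 ± 2.98 and 10.1 ± 3.23. Of 13 T and NK cell genes 3 were detected, led by Nkg7 at 25.8 ± 12, and the list shifted by 0.04 at percentile 65.9. Of 11 macrophage genes 4 were detected, Cd68 at 32.5 ± 6.52 and the complement genes C1qa, C1qb and C1qc between 2.81 and 5.04. Of 11 genes of stroma and endothelium 3 were detected, Pdgfrb at 8.37 ± 3.68 being the highest. Of 12 interferon response genes 6 were detected, with Bst2 at 238 ± 3.01 and Irf7 at 63.5 ± 23.4.

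Some lists lay above the central 95% of random lists in level and did not stand apart between the libraries: ribosomal proteins (shift 0.06, percentile 79.4), heme synthesis (0.07, percentile 70.5) and DNA replication (0.10, percentile 85.2). Against genes detected in both libraries alone the heme list fell to percentile 94.2 in level. Within it Alas1 was at 161 in replicate 1 and 81.1 in replicate 2. Of the immediate early and heat shock list, Jun was at 1610 ± 470 and Junb at 1307 ± 4.08. Among mitochondrial genes, mt-Co3 was at 0.24 in replicate 1 and 65.1 in replicate 2 and mt-Co2 at 0 and 0.01, and nuclear copies of the same sequence share their reads, so both are uncertain; mt-Co3 was picked after its values were seen.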
